A study of Homo sapiens with 4 samples.

How the data were processed

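Total RNA of HCT116 cells was made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols, for 2 control and 2 ARID1A knockdown samples. The authors deposited 1 table of FPKM values per library, fragments normalized to transcript length and to the mapped total, per the file headers. The build was GRCh38 and the tools STAR and Cufflinks, per the submitters' processing notes. Tool versions, annotation release, strand setting and any filter are not given in the sources used here. The kit is not stated to keep strand, so reads of overlapping and antisense genes cannot be told apart.

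Each table held 60811 rows keyed by gene symbol and locus, without gene identifiers. The 34 second copies of pseudoautosomal genes were dropped, leaving 60777 features, and 2347 values under 1e-9 were set to 0. Summed FPKM was 788299.6 and 781746.9 in the controls and 787114.7 and 814458.7 in the knockdown libraries. Loci are on GRCh38, with 1 added to each start that the files give. Gene types and transcript lengths came from GENCODE release 29. Of the tested features, 13297 matched it by symbol and 7047 had an identical locus, so the files used another annotation. A type was found for 13491, of which 11942 were protein coding.

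FPKM values are not counts, so no count model was used. The depth was estimated from genes with 1 annotated transcript of at least 1500 bases, whose low FPKM values fall on whole fragments. The estimates were 68500000, 71250000, 76000000 and 74500000 fragments (control 1 and 2, knockdown 1 and 2). With these, 86.5%, 83.5%, 85.0% and 85.3% of the values up to 8 fragments were whole within 0.1 fragment, against 20.6% to 21.7% after scrambling. With these totals, a chi-square comparison of the same kind of genes gave 3.84 per degree of freedom between the controls (816 genes; median over genes 1.078) and 3.34 between the knockdown libraries (835 genes; median 1.039). This argues against a duplicated library. It does not show that replicates were separate cultures, since library preparation alone adds spread.

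The comparison was knockdown minus control on log2(FPKM + 1), with a mean FPKM of at least 1 over the 4 libraries as filter. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), and genes past a Benjamini-Hochberg adjusted p of 0.05 were called. The prior had 2.79 degrees of freedom. ARID1A also had an exact two-sided permutation test. Lists of genes, 33 in all, were fixed before the data were examined, and the 28 with at least 5 tested members were tested with camera at a preset correlation of 0.01. The estimated correlation and fry, which asks whether the members of a list move, on balance, one way, were run beside it. Unlike camera, fry does not compare a list with the other tested genes. With 37.1% of all tested genes called, a list can pass fry without moving more than other genes. Of the 11 lists past camera, 0 held with an estimated correlation. Fry passed 21 lists, among them each list past camera except ribosomal proteins. With 4 libraries the estimated correlation, and the test that uses it, rest on 2 residual degrees of freedom. A call could thus be lost without a high correlation. The estimate was -6.7e-04 for the interferon list, 0.388 for ribosomal proteins, 0.355 for mitochondrial mRNAs and 0.228 for histones. Where members vary together that much, the preset of 0.01 can make the camera p too small. The lists covered interferon-stimulated genes, nucleic acid sensing, MHC class I and II, cytokines, NF-kB, immune checkpoints, SWI/SNF, heterochromatin factors, retrovirus-derived genes, cancer-testis genes, imprinted genes, ZNF genes, protocadherins, histones, p53, mitosis, DNA replication, repair, MYC, WNT, colon differentiation, mesenchymal and epithelial genes, sterol synthesis, hypoxia, ATF4, immediate early genes, mitochondrial mRNAs, ribosomal proteins and markers of leukocytes, fibroblasts and endothelium.

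The genes named were fixed by a rule written before the data were examined. It took ARID1A, ARID1B, SMARCA4, TRIM28 and SETDB1. It added the 10 largest rises and 10 largest falls by log2 change among called genes with a symbol that is not a clone name, a mean of at least 2 FPKM in the higher group and groups that did not overlap. It also took up to 3 called members of each list by absolute log2 change, or the member with the highest mean where none passed. Other genes are said to be chosen after their values were seen, as were IFNB1, IFNL1, IFNL2, IFNL3, CGAS, PTPRC and TYROBP, given as levels. Some genes that these choices take are not reported here.

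The fit was tested on simulated data built from the means and spreads of the 13607 tested genes, in 5 runs with 200 genes changed each. It recovered 2.0% of the genes changed by a log2 of 0.25, 42.4% at 0.5, 74.0% at 1 and 94.0% at 2, and 5.18% of its calls were false. A list shifted by 0.3 was found in 5 of 5 runs, with 0 other lists called. These simulations hold few changed genes, and the adjusted threshold is laxer where many genes change. Noise was also drawn for each gene independently. The 0 other lists called therefore do not show how camera behaves where members vary together. Ribosomal proteins, for example, had an estimated correlation of 0.388.

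Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, filters of 0.1, 5 and none, rescaling to TPM or by median-of-ratios factors, quantile normalization, eBayes without trend or robust, the replicate number as a block, protein-coding genes only, a log2 limit of 1, each library left out in turn, and the other list tests. Removal of length and GC trends (loess, span 0.3) was added after the data were seen. Where a library was left out, the lone sample of its group was assumed to vary like the other group. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.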

Results

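RNA was sequenced from HCT116 cells, an established human colon carcinoma line, in 2 groups of 2 libraries each. The first group was labelled control and the second carried a short hairpin RNA against ARID1A, a DNA-binding subunit of the SWI/SNF chromatin remodelling complex. The stated purpose was to ask how ARID1A relates to immune functions. Expression was read as fragments normalized to transcript length and to the mapped total (FPKM) for 60777 features, of which 13607 had a mean FPKM of at least 1 and were tested. The normalizing totals recovered from the steps between low values were about 68500000 and 71250000 fragments in the controls and 76000000 and 74500000 in the knockdown libraries. At that depth an FPKM of 1 over 2 kb rests on 137 to 152 fragments. This leaves out the correction for fragment length made in the estimate, which lowers the number for a 2 kb transcript. Mitochondrially encoded transcripts took 4.35% and 4.29% of the summed FPKM in the controls and 6.04% and 5.65% in the knockdown libraries. The labels do not say that replicates were separate cultures, so the p-values below measure the spread between these samples, which may be technical. Adjusted p-values are Benjamini-Hochberg values from limma (genes) or its camera test (gene lists), or from fry where it is named. Fry does not compare a list with other genes, so a list past fry alone is not shown to differ from them. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

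The target was examined first. ARID1A, on GRCh38 chromosome 1 from 26693236 to 26782104, was at 11.1 and 11.4 FPKM in the 2 control libraries and at 7.05 and 6.13 FPKM in the 2 knockdown libraries. Its mean fell from 11.2 ± 0.186 to 6.59 ± 0.656 FPKM (SD, n = 2), a log2 change of -0.69 (SE 0.077) with a limma adjusted p of 0.00439. An exact two-sided permutation test gave p = 0.333, the smallest p that 2 libraries against 2 can give. Its paralog ARID1B was at 8.05 ± 0.563 FPKM in the controls and 7.74 ± 0.202 in the knockdown, and the ATPase gene SMARCA4 at 18.96 ± 0.313 and 17.9 ± 0.401. Neither passed the test (limma adjusted p = 0.605 and 0.241). TRIM28, a corepressor that recruits histone methyltransferases to heterochromatin, was at 329 ± 1.09 and 325 ± 0.024 FPKM (adjusted p = 0.746). SETDB1, an H3K9 methyltransferase, was at 16.4 ± 0.142 and 13.9 ± 1.64 FPKM (adjusted p = 0.0966; 0.0336 without knockdown replicate 1). Of 26 tested SWI/SNF subunit genes, a list without ARID1A, 3 rose, 6 fell and 17 did not pass (3 and 6 adjusted over the list alone; camera adjusted p = 0.421). Across all tested genes 37.1% were called, so these counts do not set the subunit genes apart. The ATPase gene SMARCA2 fell from 4.25 ± 0.491 to 2.78 ± 0.115 FPKM, ACTL6A from 51.7 ± 0.442 to 38.2 ± 5.97 and PHF10 from 25.5 ± 0.44 to 20.4 ± 0.863. Each of these 3 calls was lost without at least 1 library. SMARCA2 was lost without control replicate 2 (adjusted p = 0.0882), knockdown replicate 1 (0.0669) or knockdown replicate 2 (0.0795). ACTL6A was lost without control replicate 1 (0.125) or 2 (0.133), and its log2 change of -0.44 became -0.28 without knockdown replicate 2. PHF10 was lost without control replicate 1 (0.0675) or 2 (0.0565).

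**Figure D1:**
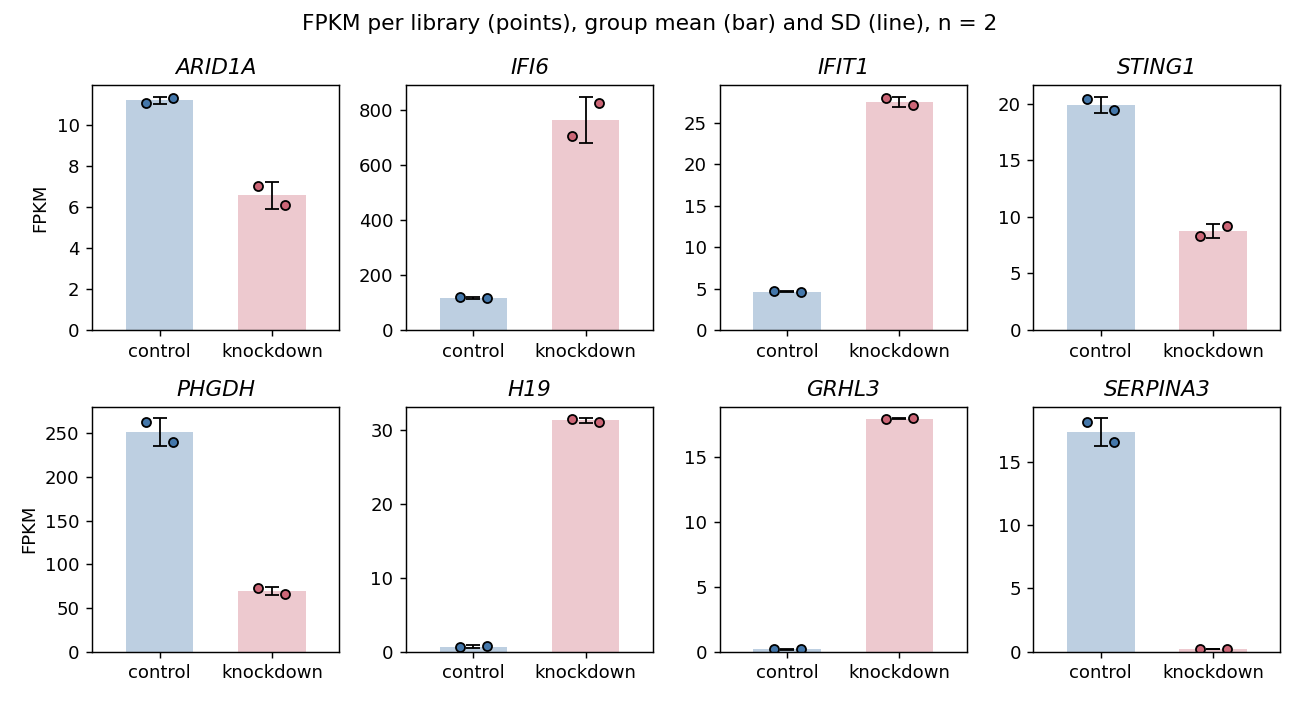
FPKM (y axes, from 0) of 8 genes in each library, with bars for group means and lines for the SD (n = 2 libraries per group). ARID1A falls from 11.2 to 6.59 FPKM, IFI6 rises from 117 to 764, and in each panel the knockdown libraries lie outside the range of the controls.

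Across all tested genes, 2481 rose and 2565 fell in the knockdown, 5046 together (37.1%), while 6594 had an unadjusted p under 0.05. Most changes were small, with a median absolute log2 change of 0.36 among the changed genes. A log2 change of at least 1 was reached by 133 of the genes that rose and 147 of those that fell. The number of changed genes was 2146 without control replicate 1, 2186 without control replicate 2, 3251 without knockdown replicate 1 and 3368 without knockdown replicate 2. Groups did not overlap for 72.3% of tested genes, where the average over all splits into pairs is 33.3%. Genes vary together across libraries, so the difference between these shares does not measure chance. The first principal component held 68.4% of the variance and the second 17.6%.

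On the log2(FPKM + 1) scale the largest rise was that of H19, an imprinted long noncoding RNA on chromosome 11 (1995176 to 2001470), which went from 0.690 ± 0.171 to 31.2 ± 0.288 FPKM (SD, n = 2), 45.3-fold (limma adjusted p = 1.68e-04). GRHL3, a transcription factor of surface epithelia on chromosome 1 (24319322 to 24364482), rose from 0.198 ± 0.0374 to 18.0 ± 0.0162 FPKM, a larger ratio of means at 90.8-fold. The uroplakin genes UPK3B and UPK2, which encode urothelial membrane proteins, rose 27.6-fold to 12.8 ± 1.19 FPKM and 24.0-fold to 6.24 ± 0.342 FPKM. GAST, encoding the hormone gastrin, rose 12.6-fold to 12.2 ± 2.02 FPKM, and SCG2, a granin of secretory granules, 7.06-fold to 53.2 ± 0.0688 FPKM. The interferon-stimulated genes IFI6 and IFI27 completed the protein-coding genes among the 10 largest rises. Of the largest falls, the acute-phase protease inhibitor gene SERPINA3, on chromosome 14 (94612384 to 94624055), went from 17.4 ± 1.1 to 0.211 ± 0.0194 FPKM, 82.2-fold lower. SERPINA1, which encodes alpha-1-antitrypsin, was 11.4-fold lower, SERPINF1 8.54-fold, the secreted protease inhibitor gene SLPI 6.73-fold and MIA 16.0-fold. ADAM19 fell from 59.2 ± 0.603 to 10.5 ± 0.328 FPKM, PKIB from 46.6 ± 0.881 to 8.52 ± 0.201, KIAA0040 from 38.1 ± 0.0075 to 7.59 ± 0.0786 and CTHRC1 from 27.8 ± 0.503 to 5.42 ± 0.599. Short features also entered these ranks and are uncertain, because they can share reads with a parent gene or host transcript. The pseudogene ATP5MDP1 and the small nucleolar RNA SNORD17 were listed at 0 in both controls, and the pseudogene MT1P3 at 0 in both knockdown libraries. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Among the protein-coding genes above, this applies to GRHL3 (overlapping STPG1), UPK2 (BCL9L) and ADAM19 (CYFIP2). It also applies to several genes named below, such as IFIT1 (LIPA), TGFB1 (HNRNPUL1), DDIT3 (MARS1) and RNF43 (SUPT4H1).

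**Figure D2:**
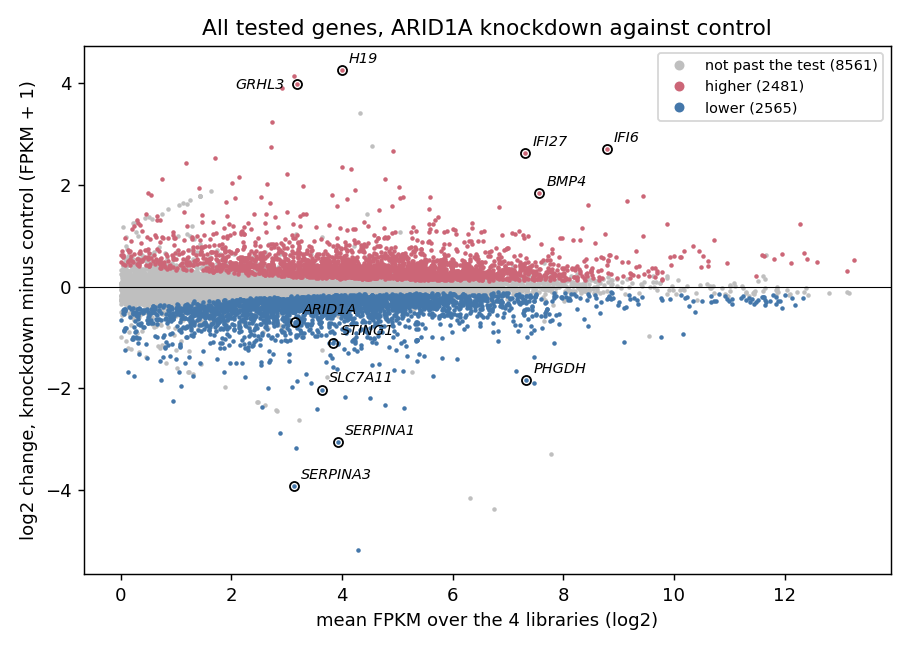
Each point is 1 of the 13607 tested genes, with mean FPKM over the 4 libraries on a log2 x axis and the log2 change (FPKM + 1), knockdown minus control, on the y axis. Red marks the 2481 genes that rose, blue the 2565 that fell and grey the rest, and most coloured points lie within a log2 change of 1 on either side of 0.

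Interferon-stimulated genes rose as a group. Of 36 tested type I and III interferon-stimulated genes, 28 rose, 2 fell and 6 did not pass (30 rose and 3 fell adjusted over the list alone), with a median log2 change of 0.66. The camera adjusted p was 3.92e-12 with the preset correlation, and the call was lost with an estimated correlation (adjusted p = 0.327 with an estimated correlation). IFI6 rose from 117 ± 3.09 to 764 ± 84.3 FPKM (SD, n = 2), 6.54-fold, and IFI27 from 43.7 ± 0.453 to 274 ± 21.7, 6.26-fold. IFIT1, which binds foreign RNA ends, rose from 4.60 ± 0.0792 to 27.6 ± 0.61 FPKM. The ubiquitin-like modifier gene ISG15, chosen after its values were seen, rose 3.44-fold. The 2 that fell, also outside the rule for named genes, were IFITM2 (244 ± 7.88 to 163 ± 13.0 FPKM) and BST2 (20.9 ± 0.445 to 18.0 ± 0.847). Between 24 and 26 members rose when any 1 library was left out. The interferon genes IFNB1, IFNL1, IFNL2 and IFNL3 were below the filter and not tested. IFNL3 was at 0.14 and 0 FPKM in the controls and 0.298 and 0.276 in the knockdown libraries, IFNL2 at 0 and 0 against 0.207 and 0.091, and IFNL1 at 0.181 and 0 against 0.218 and 0.084. IFNB1 was at 0.027 FPKM in 1 control and 0 elsewhere.

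Genes that detect cytosolic nucleic acids moved both ways. Of 16 tested, 5 rose and 3 fell (6 and 3 adjusted over the list alone), and the list did not pass camera (camera adjusted p = 0.334). It did pass fry, upward (fry adjusted p = 0.00124). STING1, the adaptor of cytosolic DNA sensing, fell from 19.9 ± 0.708 to 8.75 ± 0.662 FPKM (SD, n = 2). The RNA sensor gene IFIH1 rose from 6.27 ± 0.157 to 12.2 ± 0.0385 FPKM and the adaptor gene TICAM1 from 13.3 ± 0.834 to 19.8 ± 0.458. The DNA sensor gene CGAS was at most at 0.01 FPKM in any library.

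MHC class I antigen presentation genes rose in the main, but HLA-B and HLA-C moved in opposite directions. Of 18 tested, 11 rose and 4 fell, also when adjusted over the list alone, with a median log2 change of 0.29 (camera adjusted p = 0.0218; adjusted p = 0.366 with an estimated correlation). The list call was also lost without control replicate 1 (adjusted p = 0.0530), with a filter of at least 5 FPKM (0.0716) and under quantile normalization (0.0529). The peptide transporter gene TAP2 rose from 13.1 ± 1.41 to 20.5 ± 0.357 FPKM (SD, n = 2), the proteasome activator gene PSME2 from 110 ± 1.89 to 167 ± 2.74 and HLA-F from 18.7 ± 0.55 to 26.7 ± 2.33. The call of HLA-F was lost without control replicate 1 (adjusted p = 0.0570). Among genes chosen after their values were seen, HLA-B fell from 241 ± 17.6 to 174 ± 21.6 FPKM and HLA-E from 111 ± 0.68 to 102 ± 0.8, while HLA-C rose from 225 ± 1.5 to 259 ± 3.37. B2M was at 1521 ± 23.0 and 1581 ± 65.3 FPKM (adjusted p = 0.363). The calls of HLA-B (adjusted p = 0.0659 and 0.110) and HLA-C (0.0779 and 0.0870) were lost without control replicate 1 or 2. That of HLA-E was lost without control replicate 1 (0.152) or 2 (0.182) and without knockdown replicate 1 (0.0990) or 2 (0.0792). HLA genes share near-identical sequence, so their values are uncertain. The HLA-B (31269491 to 31357188) and HLA-C (31268749 to 31272130) features also overlap on chromosome 6. Reads there cannot be told apart, so the contrast between HLA-B and HLA-C is uncertain. Of 6 tested MHC class II genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.546; fry adjusted p = 0.0360, upward). HLA-DRB1 rose from 0.881 ± 0.0596 to 1.68 ± 0.0117 FPKM and HLA-DPA1 from 3.34 ± 0.114 to 4.55 ± 0.0133, and HLA-DRA fell from 4.96 ± 0.393 to 3.34 ± 0.289. Without control replicate 1 or 2, or knockdown replicate 1 or 2, HLA-DRB1 had an adjusted p of 0.0722, 0.0908, 0.0694 and 0.0694, and HLA-DPA1 of 0.0677, 0.0861, 0.0748 and 0.0772. The call of HLA-DRA was lost without control replicate 1 (0.0931) or 2 (0.0565) or knockdown replicate 2 (0.0735).

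The cytokine, NF-kB and checkpoint lists did not pass camera in the main fit. Fry passed each of them downward (fry adjusted p = 0.0482, 0.0224 and 0.0137). Of 40 chemokine and cytokine genes, 11 were tested, of which 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.348). CXCL8, a neutrophil attractant, fell from 1.95 ± 0.214 to 0.478 ± 0.0534 FPKM (SD, n = 2), CXCL1 from 1.45 ± 0.0043 to 0.555 ± 0.209 and TGFB1 from 34.4 ± 0.0632 to 27.1 ± 0.921. The call of CXCL1 was lost without knockdown replicate 2 (adjusted p = 0.0629). Of 24 NF-kB response genes, 3 rose and 9 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.341), among them the adhesion molecule gene ICAM1 (5.98 ± 0.485 to 2.78 ± 0.293 FPKM), TNFAIP8 (25.6 ± 0.343 to 15.9 ± 0.517) and IER3 (400.9 ± 3.5 to 259 ± 3.33). Of 19 immune checkpoint and T or NK cell ligand genes, 4 rose and 10 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.217). That list passed downward with no filter (adjusted p = 0.0227). LGALS9 fell from 2.04 ± 0.464 to 0.495 ± 0.0268 FPKM, and the ligands of the NK cell receptor NKG2D MICB and ULBP1 fell from 13.2 ± 0.484 to 6.60 ± 0.108 and from 9.88 ± 0.597 to 5.37 ± 0.215.

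**Figure D3:**
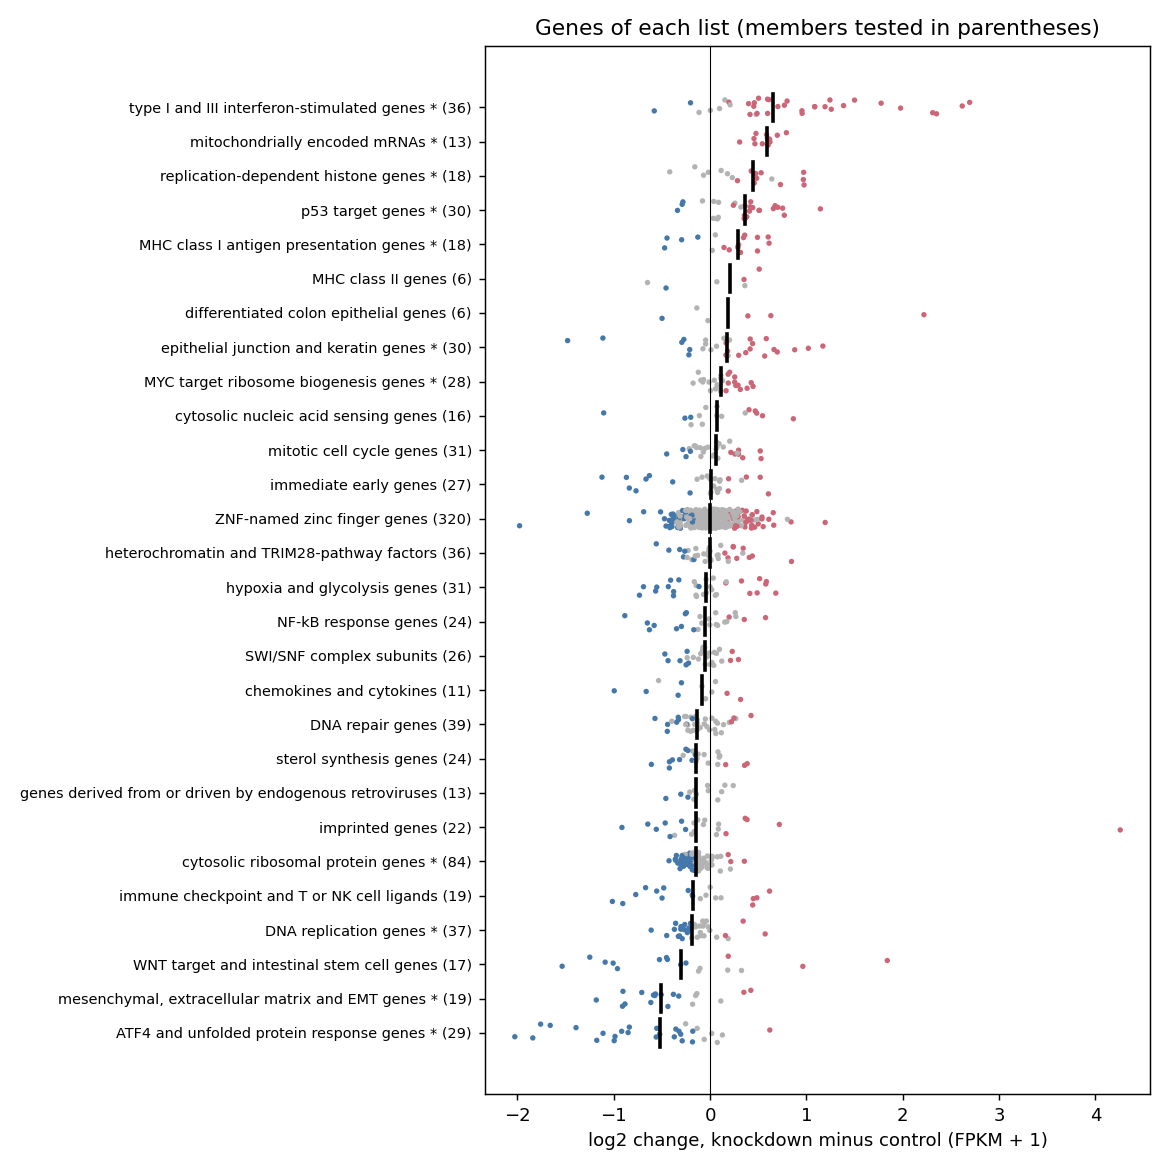
Each point is a tested member of a gene list, placed by its log2 change (FPKM + 1), knockdown minus control, on the x axis. Lists are ordered by their median (black bar), red points rose, blue points fell, grey points did not pass, and an asterisk marks the 11 lists past the camera test with the preset correlation, from the interferon list at a median of 0.66 to the ATF4 list at -0.52.

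Genes of the ATF4 and unfolded protein response fell. Of 29 tested, 22 fell, 1 rose (SDF2L1, outside the rule) and 6 did not pass (23 fell and 2 rose adjusted over the list alone), with a median log2 change of -0.52 (camera adjusted p = 2.42e-09; adjusted p = 0.327 with an estimated correlation). The cystine transporter gene SLC7A11 fell from 20.6 ± 0.831 to 4.32 ± 0.156 FPKM (SD, n = 2). PHGDH, which starts serine synthesis, fell from 251 ± 15.8 to 69.5 ± 4.36 FPKM, and TRIB3 from 78.2 ± 2.53 to 22.4 ± 0.289. Among genes chosen after their values were seen, ASNS fell 3.18-fold, PSAT1 2.64-fold and DDIT3 2.21-fold.

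All 13 mitochondrially encoded mRNAs rose, also when adjusted over the list alone, with a median log2 change of 0.60 (camera adjusted p = 6.68e-09; adjusted p = 0.366 with an estimated correlation). MT-ND2 rose from 947 ± 19.9 to 1640 ± 24.98 FPKM (SD, n = 2), MT-ND6 from 488 ± 8.8 to 793 ± 10.3 and MT-ND1 from 357 ± 12.9 to 550 ± 6.48, all subunits of respiratory complex I. Of 84 cytosolic ribosomal protein genes, 35 fell and 3 rose (36 and 3 adjusted over the list alone), with a median log2 change of -0.15 (camera adjusted p = 2.96e-06; adjusted p = 0.554 with an estimated correlation). The list did not pass fry (fry adjusted p = 0.0711), and its estimated correlation was 0.388. RPL10 fell from 4531 ± 1.63 to 3374 ± 82.7 FPKM, RPS3 from 3605 ± 108 to 2807 ± 33.3 and RPS23 from 5224 ± 93.2 to 4079 ± 40.8. The calls of RPS3 and RPS23 were lost without control replicate 2 (adjusted p = 0.0541 and 0.0557). Ribosomal protein genes have many processed pseudogenes that can share their reads.

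Growth and cell cycle lists moved in different directions. Of 30 tested p53 target genes, 19 rose and 3 fell (21 and 3 adjusted over the list alone), with a median log2 change of 0.36 (camera adjusted p = 1.11e-05; adjusted p = 0.327 with an estimated correlation). SFN, encoding a 14-3-3 protein of the G2 checkpoint, rose from 201 ± 1.18 to 447 ± 7.4 FPKM (SD, n = 2), BTG2 from 14.9 ± 0.512 to 26.2 ± 0.129 and SESN1 from 5.74 ± 0.112 to 10.4 ± 0.454. Of genes chosen after their values were seen, the cyclin-dependent kinase inhibitor gene CDKN1A rose 1.34-fold, and MDM2 was at 33.1 ± 0.432 and 34.1 ± 3.72 FPKM (adjusted p = 0.757). The 3 that fell, outside the rule, were SESN2, GADD45A and TNFRSF10B. Of 37 DNA replication genes, 17 fell and 3 rose, also adjusted over the list alone, with a median log2 change of -0.18 (camera adjusted p = 0.00171; adjusted p = 0.327 with an estimated correlation). GINS4 fell from 16.2 ± 1.82 to 10.3 ± 0.544 FPKM and the licensing factor gene CDT1 from 38.9 ± 1.93 to 28.3 ± 1.78, while CCNE1 rose from 23.9 ± 1.05 to 36.0 ± 0.123. The call of CDT1 was lost without control replicate 1 (adjusted p = 0.0524). Of 31 mitotic genes, 7 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.458; fry adjusted p = 0.0252, upward). Among them were KIF20A (7.80 ± 0.018 to 11.7 ± 0.131 FPKM), CDC20 (45.2 ± 1.32 to 65.4 ± 1.7) and NDC80 (14.3 ± 0.449 to 10.2 ± 0.2).

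Of 18 tested replication-dependent histone genes, 10 rose and 0 fell (10 and 1 adjusted over the list alone), with a median log2 change of 0.44 (camera adjusted p = 0.00414; adjusted p = 0.513 with an estimated correlation). The linker histone gene H1-2 rose from 18.98 ± 1.18 to 38.3 ± 0.664 FPKM (SD, n = 2), H2AC7 from 0.612 ± 0.261 to 2.17 ± 0.585 and H2BC4 from 2.15 ± 0.712 to 5.08 ± 0.0291. The median was 0.29 with a filter of at least 0.1 FPKM and 0.16 with no filter. The call of H2AC7 was lost without control replicate 1 (adjusted p = 0.0827) and that of H2BC4 without knockdown replicate 1 (0.0596). Histone genes are near-identical copies and their values are uncertain. Of 28 MYC target genes of ribosome biogenesis, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 change of 0.12 (camera adjusted p = 0.00357; adjusted p = 0.366 with an estimated correlation). NOP16 rose from 45.2 ± 0.744 to 62.0 ± 0.793 FPKM, TFB2M from 23.2 ± 0.0172 to 31.6 ± 0.488 and PES1 from 47.5 ± 1.69 to 62.4 ± 0.023. Of 39 DNA repair genes, 3 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.117). The list passed downward with no filter (adjusted p = 0.0422). RNASEH2B fell from 20.8 ± 2.85 to 13.6 ± 0.216 FPKM, RNASEH2A from 26.5 ± 2.76 to 19.2 ± 0.526 and XRCC3 from 14.6 ± 1.09 to 10.5 ± 0.403. The calls of RNASEH2B and RNASEH2A were lost without knockdown replicate 1 (adjusted p = 0.0582 and 0.0653), and that of XRCC3 without control replicate 1 (0.0524).

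Mesenchymal and extracellular matrix genes fell while epithelial junction and keratin genes rose in the main. Of 19 tested mesenchymal genes, 13 fell and 2 rose, also adjusted over the list alone, with a median log2 change of -0.51 (camera adjusted p = 7.23e-04; adjusted p = 0.327 with an estimated correlation). The median was -0.31 with a filter of at least 0.1 FPKM and -0.15 with no filter. The matricellular gene CCN2 fell from 2.81 ± 0.106 to 0.683 ± 0.0106 FPKM (SD, n = 2) and LOXL2 from 25.2 ± 1.48 to 13.0 ± 0.161. Of 30 epithelial genes, 16 rose and 6 fell (17 and 6 adjusted over the list alone), with a median log2 change of 0.18 (camera adjusted p = 0.0119; adjusted p = 0.396 with an estimated correlation). The transcription factor gene OVOL1 rose from 6.68 ± 0.109 to 16.3 ± 0.49 FPKM. In the other direction, EPCAM, an epithelial adhesion molecule gene, fell from 312 ± 0.233 to 144 ± 4.27 FPKM and the desmosomal gene DSC2 from 9.92 ± 0.178 to 2.92 ± 0.0468.

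Of 17 WNT target and intestinal stem cell genes, 3 rose and 10 fell (4 and 10 adjusted over the list alone), with a camera adjusted p of 0.0653. The list passed with a filter of at least 0.1 FPKM (0.0403), with no filter (0.0486) and under quantile normalization (0.0430). It also passed fry, downward (fry adjusted p = 0.00206). NOTUM fell from 35.02 ± 1.29 to 11.4 ± 0.407 FPKM (SD, n = 2) and RNF43, a negative regulator of WNT receptors, from 44.6 ± 0.0496 to 18.2 ± 0.0353. AXIN2 and SOX9, chosen after their values were seen, fell 2.10-fold and 2.03-fold. BMP4, a secreted growth factor gene, rose from 82.0 ± 0.158 to 296 ± 2.01 FPKM. Of 32 differentiated colon epithelial genes, 6 were tested, of which 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.286; fry adjusted p = 0.0343, upward). KRT20 rose from 2.21 ± 0.289 to 13.9 ± 0.564 FPKM and KLF4 from 22.9 ± 1.21 to 36.0 ± 0.8, and CEACAM1 fell from 2.50 ± 0.247 to 1.49 ± 0.318. The call of CEACAM1 was lost without control replicate 1 (adjusted p = 0.0999) or 2 (0.165) or knockdown replicate 2 (0.117).

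Of 24 sterol synthesis genes, 3 rose and 9 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.0653). The list passed with a filter of at least 0.1 FPKM (0.0403), no filter (0.0123), quantile normalization (0.0222) and length and GC trends removed (0.0437). It also passed fry, downward (fry adjusted p = 0.0224). CYP51A1 fell from 69.9 ± 1.19 to 51.9 ± 0.351 FPKM (SD, n = 2) and SREBF2, which encodes the activator of this pathway, from 88.3 ± 0.596 to 65.7 ± 1.22. Of 31 hypoxia and glycolysis genes, 8 rose and 10 fell (9 and 11 adjusted over the list alone; camera adjusted p = 0.546). CA9 fell from 4.19 ± 0.191 to 2.12 ± 0.0183 FPKM and VEGFA from 51.1 ± 2.91 to 31.3 ± 0.0563, and KDM3A rose from 13.6 ± 0.737 to 22.5 ± 1.27. Of 27 immediate early genes, 5 rose and 8 fell, also adjusted over the list alone, and the list did not pass camera (camera adjusted p = 0.636, directed down, against a median of 0.01 and a mean of -0.11). Fry passed it downward (fry adjusted p = 0.00988). JUN fell from 21.2 ± 0.354 to 9.20 ± 0.295 FPKM, ETV5 from 40.1 ± 1.12 to 21.5 ± 0.354 and ATF3 from 26.5 ± 1.47 to 14.4 ± 0.547.

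Genes tied to heterochromatin showed no shift as lists. Of 36 heterochromatin and TRIM28-pathway factors, 9 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.751, directed up, with a median of -0.0034 and a mean of 0.022). L3MBTL3 rose from 14.8 ± 0.915 to 27.5 ± 1.34 FPKM (SD, n = 2) and the HP1 beta gene CBX1 from 77.6 ± 1.16 to 106 ± 4.83, and SMCHD1, a factor of the inactive X chromosome, fell from 15.2 ± 0.786 to 9.99 ± 0.298. Of 320 ZNF-named zinc finger genes, 36 rose and 37 fell (21 and 22 adjusted over the list alone; camera adjusted p = 0.815, directed up, with a median of -6.6e-04 and a mean of 0.0041). ZNF704 fell from 14.3 ± 4.07 to 2.83 ± 0.255 FPKM, ZNF532 from 9.54 ± 0.286 to 3.36 ± 0.183, and ZNF488 rose from 1.01 ± 0.0131 to 3.61 ± 0.359.

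Of 30 genes derived from or driven by endogenous retroviruses, 13 were tested, of which 0 rose and 3 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.361). Fry passed the list downward (fry adjusted p = 0.0119). ERVMER34-1 fell from 9.23 ± 0.355 to 6.45 ± 0.0651 FPKM (SD, n = 2), HHLA3 from 17.9 ± 0.521 to 14.3 ± 1.06 and RTL10 from 6.58 ± 0.124 to 5.47 ± 0.0577. Without control replicate 1 or 2, or knockdown replicate 1 or 2, RTL10 had an adjusted p of 0.144, 0.113, 0.130 and 0.114. The call of HHLA3 was lost without control replicate 1 (0.114) or 2 (0.0831) or knockdown replicate 1 (0.0727). Copies of retroviral repeats themselves were not analysed here. Of 22 imprinted genes, 5 rose and 7 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.389, directed down, with a median of -0.15 and a mean of 0.07). GRB10 fell from 19.2 ± 1.12 to 9.73 ± 0.272 FPKM and DIRAS3 rose from 2.57 ± 0.554 to 4.84 ± 0.411. IGF2, the neighbour of H19 and chosen after its values were seen, fell from 14.5 ± 0.22 to 10.3 ± 1.2 FPKM. The call of IGF2 was lost without control replicate 1 (0.0820) or 2 (0.0732), and that of DIRAS3 without control replicate 2 (0.0511) or knockdown replicate 1 (0.0503) or 2 (0.0650).

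Lists with fewer than 5 tested members had no list test. Of 46 cancer-testis genes, 4 passed the filter, and 3 of these rose, also adjusted over the list alone. MAGEB2 rose from 114 ± 0.329 to 140 ± 1.17 FPKM (SD, n = 2), MAGEA2 from 28.6 ± 0.952 to 32.8 ± 0.68 and MAGEA3 from 58.5 ± 1.58 to 66.0 ± 0.736. Without control replicate 1 or 2, or knockdown replicate 1 or 2, MAGEA2 had an adjusted p of 0.0813, 0.146, 0.0728 and 0.106, and MAGEA3 of 0.0831, 0.143, 0.0695 and 0.0854. These MAGEA genes are near-identical and uncertain. Of 54 clustered protocadherin genes, which share 3' exons, 3 were tested. PCDHAC1 rose from 0.725 ± 0.0968 to 1.81 ± 0.0289 FPKM and PCDHAC2 from 2.34 ± 0.348 to 4.30 ± 0.108. PCDHGA10 fell from 2.43 ± 0.243 to 1.55 ± 0.0641, with the same counts adjusted over the list alone. PCDHAC1 was lost without control replicate 2 (adjusted p = 0.0555). PCDHGA10 had an adjusted p of 0.129, 0.0742, 0.0808 and 0.101 in the 4 fits that each left out 1 library.

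Markers of other cell types were few. Of 22 leukocyte markers, 2 were tested and 0 passed (1 higher adjusted over the list alone). CORO1A was at 1.30 ± 0.403 FPKM in the controls and 2.75 ± 0.858 in the knockdown (SD, n = 2; limma adjusted p = 0.0577, and 0.0412 without knockdown replicate 2). The pan-leukocyte gene PTPRC was at most at 0.006 FPKM in any library and TYROBP was listed at 0 in each. Of 2 tested fibroblast markers, FBLN1 fell from 15.9 ± 1.08 to 10.6 ± 1.24 FPKM and 0 rose (1 and 1 adjusted over the list alone). Of 2 tested endothelial markers, EGFL7 fell from 68.4 ± 0.732 to 56.4 ± 1.71 FPKM and 0 rose, also adjusted over the list alone. The call of FBLN1 was lost without control replicate 1 (adjusted p = 0.0723), and that of EGFL7 without control replicate 1 (0.0553) or 2 (0.0626).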

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

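ARID1A and the interferon list kept their direction and their calls under each setting run that gave them a value, apart from the list test with an estimated correlation. The number of changed genes, 5046, was 2781 with no filter on low FPKM (1371 higher, 1410 lower), where 29038 genes were tested, and 280 with a log2 limit of 1. Leaving out 1 library gave between 2146 and 3368 changed genes, 1057 to 1666 higher and 1037 to 1805 lower, with fewer samples in each fit. The number of lists past the test, 11, was 0 with an estimated correlation and 21 with fry. The MHC class I median of 0.29 was 0.24 with a filter of at least 5 FPKM and 0.23 under quantile normalization, both no longer past the test, and 0.26 to 0.29 with 1 library left out. The cause was not tested. Near 0, directions turned. The heterochromatin list had medians from -0.0232 to 0.0503 with 1 library left out, and the direction of its test turned without control replicate 2 (-0.0144). The ZNF list ranged from -0.0137 to 0.0284, and its test turned without control replicate 2 and with a filter of at least 5 FPKM (0.0043). ARID1B ranged from -0.113 to 0.0139, turning without control replicate 1, and MDM2 from -0.0731 to 0.144, turning without knockdown replicate 1. None of these was past the test in any of those fits. Of the other list values, 427 kept direction and side of the threshold and 9 newly passed. Of those of named genes, 2282 kept both, 127 lost the call and 14 newly passed. The fit with a replicate block called 4126 genes, 3967 of them shared with the 5046. The labels do not say that replicate numbers pair the libraries, so they share only a number. The deviations of same-numbered libraries correlated at -0.01, a single value, since with 2 libraries per group both numbers give the same correlation. Rescaling to TPM called 43.0% of changed genes higher. In simulations with 200 changed genes, far fewer than were called here, 2.0% of log2 changes of 0.25 were recovered.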

Other observations

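The stratified epithelium, BMP and metallothionein lists were written after the largest changes were seen, with members already seen left out of their tests. The leukocyte, hairpin, scale and length and GC tests were also chosen after the main results were seen, and SFN was left out of the stratified list after its first test. Further genes of stratified and urothelial epithelia rose. Besides GRHL3, UPK3B, UPK2 and SFN, the keratin gene KRT13 rose from 1.90 ± 0.222 to 10.7 ± 0.179 FPKM (SD, n = 2), LY6D from 0.983 ± 0.127 to 7.79 ± 0.0322 and the hemidesmosomal collagen gene COL17A1 from 1.38 ± 0.0399 to 6.95 ± 0.2. The list held 35 members, of which 12 further ones were tested, and the others were already seen or not tested. Of these 12, 8 rose and 1 fell (camera p = 9.60e-04; p = 0.102 with an estimated correlation; 1.80e-04 with SFN as a further member). Among them were PPL at 1.80-fold and PERP at 1.69-fold, while the protease gene KLK6 fell 2.34-fold. A shift of these cells toward a stratified epithelial program may be one reading, and it stays a hypothesis found and tested on the same libraries.

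Targets of BMP signalling were looked at because BMP4 rose 3.61-fold with ID2 (3.03-fold), ID3 (3.22-fold) and MSX2 (3.61-fold). The BMP response list held 22 members. Of 9 further ones tested, 4 rose, GATA2 and DLX2 among them, and 2 fell, ATOH8 and GATA3 (camera p = 0.178; p = 0.462 with an estimated correlation). The prediction had counted any p of 0.05 or more against a BMP response, which a missed threshold over 9 genes cannot carry, so the test left it undecided. The calls of ATOH8 (adjusted p = 0.101, 0.0586, 0.0582 and 0.0748) and GATA3 (0.173, 0.0912, 0.140 and 0.0833) were lost in each of the 4 fits that left out 1 library. The metallothionein pseudogene MT1P3 was listed at 0 in both knockdown libraries. Of 4 tested members of a list of 9 metallothionein genes 0 passed, with MT2A at 2897 ± 110 and 3342 ± 211 FPKM. The log2 changes of all 4 were above 0, with a mean of 0.12 (SD 0.0682 over genes; camera p = 0.130; p = 0.473 with an estimated correlation), which argues against a fall of these tested members. The pseudogene ATP5MDP1 was listed at 0 in both controls, while its parent ATP5MD was at 645 ± 12.6 and 769 ± 1.26 FPKM.

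The rise of interferon-stimulated genes came with lower STING1, while IFNB1, IFNL1, IFNL2 and IFNL3 were below the filter and not tested, at no more than 0.298 FPKM in any library. A transcript length or GC trend is argued against, since the list's median log2 change was 0.68 with those trends removed. Leukocytes in the knockdown cultures are argued against as well: the summed FPKM of 22 leukocyte markers rose by 0.218 against 2411 for the interferon list, under bounds set after the values were seen, because a first form of the test, counting markers above 1 FPKM, decided nothing. A response to the hairpin or its delivery, rather than to loss of ARID1A, cannot be told apart from that loss, because the labels do not describe the control construct and 0 libraries were labelled with another hairpin or as the hairpin with intact ARID1A. The effect of ARID1A loss therefore remains among the open explanations.

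Mitochondrially encoded mRNAs rose while ribosomal protein genes fell. With length and GC trends removed the median log2 changes were 0.59 and -0.16. Those trends shifted genes by a median of 0.0163 (0.0403 at percentile 95), too little to be the whole cause. A common scale factor would move all genes alike. The median minus that of all other tested genes was 0.60 for the mitochondrial list (pooled SD between replicates 0.0180) and -0.15 for ribosomal protein genes (0.0454). This argues against such a factor as the whole cause of either, though it repeats the comparison that called the lists and its bounds and spread were set after the values were seen. A difference in RNA handling between the groups was not tested, and the biological difference named by the design remains open beside it.

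The large number of changed genes could come from a subclone with another copy number of chromosome parts. Among windows of 100 neighbouring tested genes the largest absolute median log2 change was 0.127, on chromosome 8 from 27596917 to 58659853, below the bound of 0.3 set before the result was seen. This argues against gains or losses of that extent within these windows, if carried by most cells. Shorter ones, and those in part of the cells, stay open. Genes left over at chromosome ends, too few for a window, were not examined, such as those of chromosome 18 past 39800322. The other ways to split the 4 libraries into pairs called 1 and 0 genes. Each such pair joins 1 control and 1 knockdown library, so a group difference adds to the spread within pairs and lowers the calls. For that reason, and because the splits are too few, these counts do not weigh chance.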
